A study of Homo sapiens with 6 samples.

How the data were processed

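Gene expression was measured with 1-colour Agilent arrays in 3 samples of T24 cells and 3 of T24GR cells, with Cy3-labelled cRNA made from 0.1 µg of total RNA, per the labels' protocols. The scanner files hold 62976 spots per array. Per the file headers, Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes) made the intensity values, in which the processed signal is background-subtracted and spatially detrended and very low values are replaced by small positive ones. Flags of 0 or 1 that the authors deposited mark spots well above background, saturated or non-uniform. The series value table is in log2 units as the authors deposited it: set against the arrays, it equals the processed signal scaled to the 75th percentile with each probe's median over the 6 arrays subtracted (r = 1.0 for every column), so its scale, centring and direction are settled. Its column medians were -0.16, 0.033 and -0.22 for T24 replicates 1 to 3 and 0.39, 0.89 and -0.13 for T24GR replicates 1 to 3.

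From the files, the log2 processed signal minus each array's 75th percentile was computed. Of 58717 non-control spots, those flagged as outliers were left out and spots of one probe were averaged, giving 50599 probes. Saturated spots were 0. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 24814 probes, and 32 others were left out because every spot was an outlier on some array. Probes were named through their RefSeq accession and a RefSeq gene table of the GRCh38.p14 assembly, through which 30004 probes had one symbol and 20595 had none. The array grid is on hg19 per the file headers, so no coordinates are given, and the RefSeq table was used only for names and for which genes neighbour each other or share a chromosome. Each of 14357 genes, 12947 of them protein-coding, was represented by its kept probe with the highest mean signal, and 3761 genes had more than 1 kept probe. Among called genes, 1 had another probe called the opposite way.

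The lines were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the package data.table (version 1.17.8), Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The comparison, samples, 31 lists, alternatives and the rule for named genes were fixed before the data were examined, apart from 2 alternatives named below and 2 lists in the closing section. Named genes were 5 genes of gemcitabine handling whatever their result; the 12 highest and 12 lowest log2 differences among called genes measured on all 6 arrays with no overlap between groups; up to 6 genes per direction with the largest lower-bound fold among those measured on all arrays of one group and none of the other; and, in each gene list with a call, up to 3 members per direction, or up to 2 members as values in a list without one. Symbols that are only clone or locus names were left out. A lower-bound fold sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound holds only for the processed signal with 75th percentile scaling, and normexp background correction gave smaller folds for some genes. Of 31 gene lists written from general knowledge, 29 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01; the other lists, fibroblast markers (1 measured, 1 rose) among them, were too small. Some genes that these rules chose are not reported here. With an estimated correlation 0 of the 4 calls held (lowest adjusted p = 0.60). By fry, which asks whether a list's genes move one way on balance, mitosis, cancer-testis, basal urothelial and steroid synthesis lists passed.

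Same-numbered arrays share a slide, per the file headers, and the 3 slides were scanned separately. That pairs the samples by slide. Deviations from the group means of same-numbered arrays correlated at 0.098, 0.21 and 0.35 across probes, and each array correlated best with its own number. The slide was therefore also fitted as a block, and no separate scan term was needed. Alternatives covered normexp background correction with offset 50, quantile normalization, median scaling, the authors' value table, other filters on dim probes, the mean of a gene's probes, moderation with a trend, a test against a 1.2-fold change, a test of each gene on its own variance without moderation, and each array left out in turn. The alternatives without T24GR replicates 1 and 2, and without the probes of a dim area on one array, were chosen after seeing the data. That area was found by taking, around each kept spot, the median difference from the other arrays of its group over the neighbouring spots. The scanner files have a median but no mean spot signal column, so normexp used the median signal and median background.

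The model was tested on simulated arrays with the real probe means and spreads of the T24GR against T24 comparison (24814 probes, some changed at known folds). It recovered 53% of 4-fold, 7.46% of 2-fold and 0% of 1.5-fold changes, and called 8 unchanged probes among 48 calls. At the T24 arrays' own spread, it recovered 92.4%, 65.7% and 46.3%, with 4 unchanged probes called. A simulated list of 30 genes shifted by 1 log2 unit was found among 29 lists with 0 other lists called. The simulation had no deviations shared by the genes of an array. The number of arrays, 3 per group, limits the precision of every value.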

Results

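T24 is an established human bladder cancer cell line, and T24GR is a line that the submitters derived from it by growth in gemcitabine, a deoxycytidine analog used against bladder cancer. Per the labels' protocols, selection started at 5 nM gemcitabine, lasted 3 months and ended with cells viable at 50 nM. Total RNA of 3 T24 and 3 T24GR samples was labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, 1 array per sample. The labels number the samples 1 to 3 in each group but do not say that they were separate cultures, so p-values measure the spread between these samples, which may be technical. The comparison asks which genes differ in expression between the resistant line and its parent.

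The arrays differed in brightness. Of the non-control spots, 53.3% to 55.8% were well above background on the T24 arrays, against 49.5%, 43.7% and 55.4% on T24GR arrays 1, 2 and 3. The 75th percentile of the processed signal was 438 to 520 units on the T24 arrays and 228, 189 and 439 units on the 3 T24GR arrays. T24GR arrays also differed more from one another: the SD of the log2 differences between 2 arrays was 0.298 to 0.342 for T24 pairs and 0.676 to 1.23 for T24GR pairs. T24GR replicate 3 was nearer to the T24 arrays (SD 0.841 to 0.846) than to T24GR replicate 2 (1.23). It was nearest to T24GR replicate 1 (0.676). On the T24GR replicate 2 array, 6.74% of the kept spots lay in areas where neighbouring spots were jointly dim by more than 1 log2 unit, and the other 5 arrays had no such spot. Genes measured in that area are named below as lying in the dim area. Arrays with the same number shared a slide, T24 always at one position and T24GR at another, so position and group cannot be told apart, and differences within each of the 3 slides are given for DCK and the shifted lists.

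**Figure D1:**
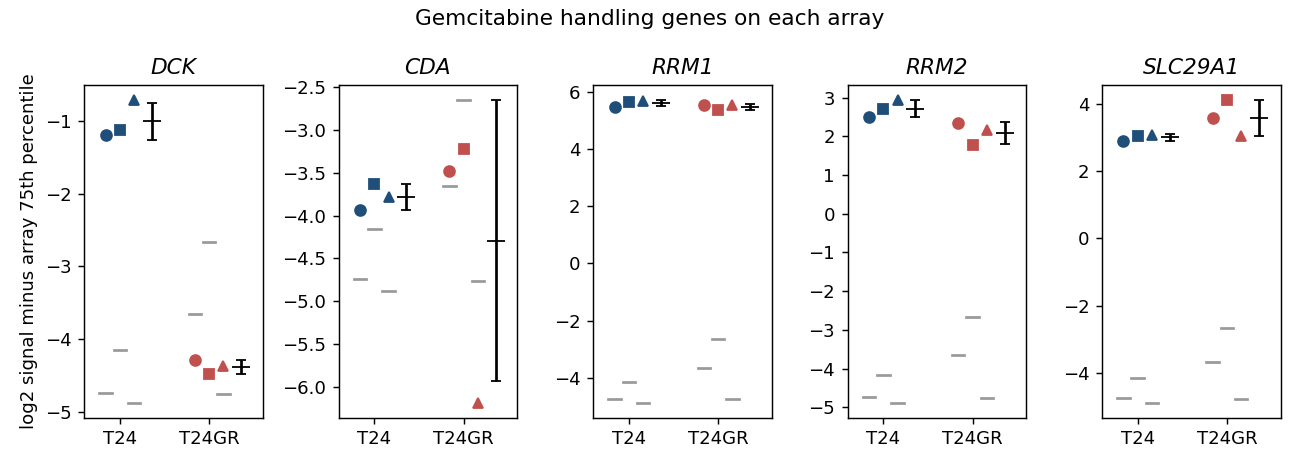
Normalised log2 signal (log2 signal minus the array's 75th percentile, vertical axis, scaled per gene) of 5 genes of gemcitabine handling in T24 (blue) and T24GR (red); circles, squares and triangles are replicates 1, 2 and 3, black bars show the mean with the SD of 3 arrays, and short grey lines mark the lowest signal well above background on each array. DCK lay between -4.49 and -4.29 in T24GR.

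DCK, deoxycytidine kinase, which adds the first phosphate to gemcitabine, was lower in T24GR. Its normalised log2 signals were -1.18, -1.11 and -0.71 in T24 and had a mean of -4.39 ± 0.10 (SD, n = 3) in T24GR. The log2 difference was -3.39 ± 0.20 (SE, limma adjusted p = 0.000264). Only 1 of the 3 T24GR arrays measured DCK, which had 1 probe, well above background. The T24GR SD, the SE and the p-value therefore rest partly on signals below the background floor. With each signal raised to its array's background floor the fall was at least 5.91-fold. DCK fell on all 3 slides, with differences of -3.11, -3.38 and -3.67. The DCK log2 difference stayed between -3.48 and -3.24 whichever array was left out, but its size depended on background correction: it was -1.58 with normexp and quantile normalization and -1.18 with normexp and the 75th percentile (limma adjusted p = 0.00162 and 0.0151). RRM1 and RRM2, the subunits of ribonucleotide reductase, differed by -0.13 ± 0.17 and -0.63 ± 0.23 log2 units (SE, limma adjusted p = 0.59 and 0.097), and RRM2 passed with normexp and quantile normalization (limma adjusted p = 0.0461). SLC29A1, a nucleoside transporter, differed by 0.57 ± 0.29 (SE, limma adjusted p = 0.19) and passed without T24GR replicate 3 (limma adjusted p = 0.0177). CDA, cytidine deaminase, which inactivates gemcitabine, was not well above background on any T24GR array, and its differences of 0.46, 0.41 and -2.40 on the 3 slides went both ways (limma adjusted p = 0.62). Leaving out T24GR replicate 3 turned the CDA log2 difference from -0.51 to 0.43. With T24GR replicate 3 as the only T24GR array the difference was -2.40, from a signal of -6.18 that lay below that array's background floor of -4.76. Of 18 measured genes of gemcitabine transport, activation and inactivation, 1 rose and 1 fell, with the same counts adjusted over the list alone. The one that rose was TK2, mitochondrial thymidine kinase, by 1.83-fold (limma adjusted p = 0.035). The TK2 call ended with the replicate block (adjusted p = 0.0502) and with median scaling (limma adjusted p = 0.0752) and held under 2 of the 6 leave-outs (highest limma adjusted p = 0.161). NR3C1, the glucocorticoid receptor, fell 1.98-fold (limma adjusted p = 0.0313), and kept its call under 2 of the 6 leave-outs (highest limma adjusted p = 0.146).

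Across 14357 genes, 1288 were higher and 1105 lower in T24GR (limma with Benjamini-Hochberg adjustment), and 950 and 818 of them by at least 2-fold. Every one of these 2393 genes moved the same way on all 3 slides. Their selection on these same 6 arrays made that likely, so it is not separate evidence. The groups did not overlap for 46.6% of genes, where chance gives 10%. Scaling moved the split between directions: 53.8% of calls were higher with the 75th percentile and 32.3% with the median, and the median log2 difference of all genes was 0.10, -0.015 after quantile normalization and -0.13 with median scaling. Leaving out T24 replicate 1, 2 or 3 left 531, 484 or 411 calls, leaving out T24GR replicate 1 left 577, leaving out T24GR replicate 3 gave 8241, and leaving out T24GR replicate 2 gave 2828. Across genes the log2 difference correlated with the length of the gene in the genome at a Spearman rho of -0.241, and the cause of this trend was not tested. In total 392 genes, 229 higher and 163 lower, were called under every one of these 6 leave-outs. Of 120 called genes that the rules for named genes chose, 59 kept their call under all 6 leave-outs and 105 under all 4 other scalings.

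Among genes measured on all 6 arrays, the largest rises in T24GR were in PDPN (podoplanin, a membrane glycoprotein), 8.97 ± 0.26 log2 units, and ACTG2 (a smooth muscle actin), 8.75 ± 0.28 (SE, limma adjusted p = 2.96e-05 and 4.24e-05). KISS1, which encodes the kisspeptin precursor, rose by 6.17 ± 0.30. GPC4, IGFBP5, FAM89A, ANGPTL2 and ITGA11, which include a heparan sulfate proteoglycan, an IGF-binding protein and a collagen-binding integrin subunit, rose by 4.34 to 5.28. The cancer-testis genes MAGEB2, XAGE2, CTAG1A and CTAG2 rose by 5.70, 5.33, 4.36 and 4.24. The largest falls were in ANXA8L1 (an annexin), by -6.62 ± 0.22, and CYB5R2 (a cytochrome b5 reductase), by -6.40 ± 0.16 (SE, limma adjusted p = 4.24e-05 and 2.64e-05). The log2 difference was -5.60 for HOXA7, a homeobox gene, -5.31 for ITGB4, the beta 4 integrin of hemidesmosomes, and -4.78 for TIMP3, a metalloproteinase inhibitor. SPOCK1 and FST, the activin antagonist follistatin, had differences of -4.63 and -4.20. Smaller falls, from -3.60 to -2.91, were found for F2RL1, ANGPTL4, RIPOR3, CPA4 and FAM174B. These 24 genes had limma adjusted p of at most 0.0066 and kept their call under each of the 6 leave-outs and 4 other scalings. CTAG1A, CTAG2, XAGE2 and ANXA8L1 have near-identical paralogs that a probe can also bind, so the gene that moved is uncertain within each family.

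**Figure D2:**
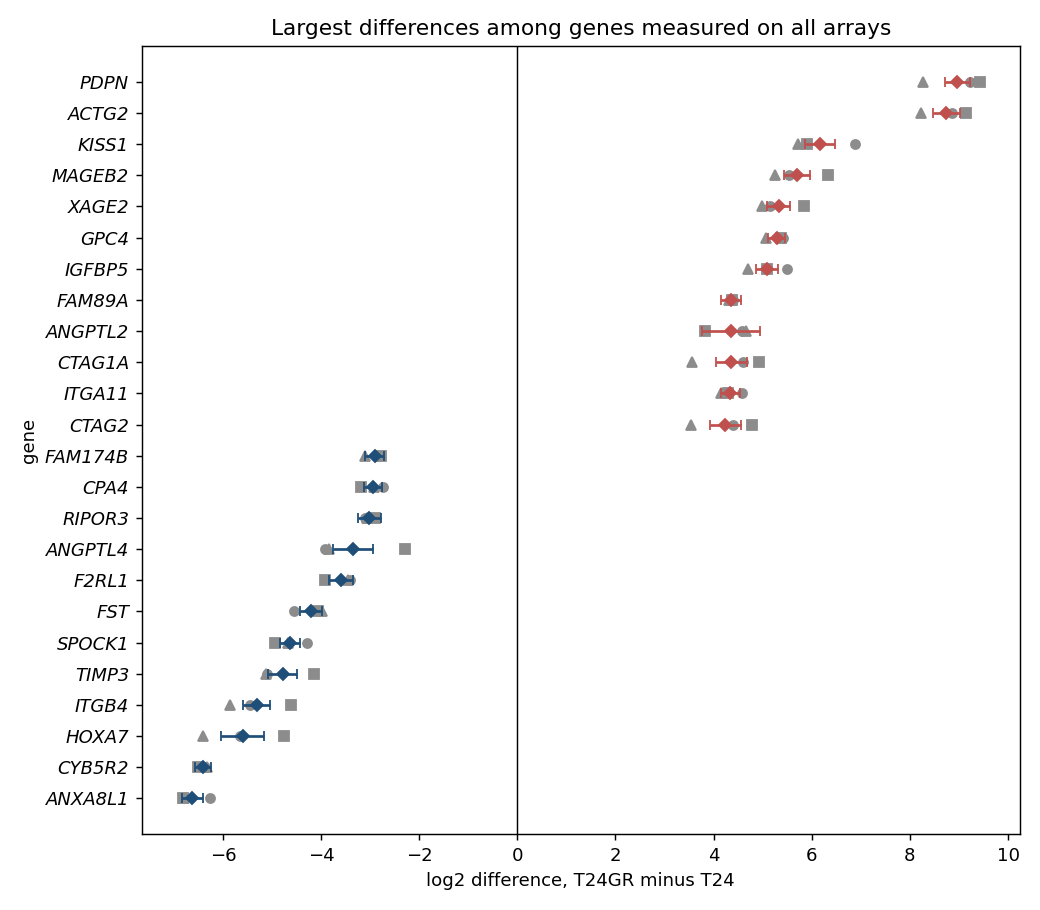
Log2 difference between T24GR and T24 (horizontal axis) of the 12 highest and 12 lowest named genes measured on all 6 arrays. Diamonds with bars give the mean difference with its SE (n = 3 and 3), and grey circles, squares and triangles are the differences within slides 1, 2 and 3; PDPN lies highest at 8.97 and ANXA8L1 lowest at -6.62.

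Some genes were measured on all 3 arrays of one line and not well above background on any array of the other, so that only a lower bound of the fold exists. Higher in T24GR were LRRC38 by at least 2379-fold, FGF13 by at least 250.5-fold, PASD1 by at least 188-fold, HS6ST2 by at least 57.6-fold, XK by at least 44.4-fold and CYP2J2 by at least 43.8-fold. They include an auxiliary subunit of potassium channels (LRRC38), a fibroblast growth factor homologue (FGF13), a cancer-testis antigen (PASD1) and an arachidonic acid epoxygenase (CYP2J2, which lay in the dim area). The 2 HS6ST2 probes differed, at 4.40 and 8.02 log2 units, and the bound is that of the brighter probe. Lower in T24GR were SGCE by at least 112.7-fold, PEG10 by at least 74.4-fold, MEST by at least 57.8-fold, EMILIN2 by at least 31.6-fold, ANXA10 by at least 19.3-fold and KRT17 by at least 18.3-fold. SGCE, PEG10 and MEST are imprinted genes, SGCE and PEG10 are neighbours, and KRT17 is a keratin of basal epithelia. Their limma adjusted p lay at or below 0.0017.

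Cancer-testis antigens, genes whose expression is normally restricted to germ cells, rose as a list. Of 29 listed genes 13 were measured, and of these 10 rose and 0 fell, and adjusted over the list alone 11 rose and 2 fell. MAGEB2 rose 52-fold and XAGE2 40.2-fold. The list median was 3.74 (3.51 with bounds in place of values not above background), and 3.56, 3.82 and 3.34 on slides 1, 2 and 3 (camera adjusted p = 8.9e-07). With an estimated correlation the camera adjusted p was 0.60, so the call did not hold. With no filter on dim probes 23 members were tested, 10 rose and 0 fell, and the list median was 1.07 (camera adjusted p = 3.29e-06). The median of all genes was then 0.398, so the list lay 0.674 above it, against 3.64 with the filter. Probes of the MAGEA, XAGE and PAGE families can bind several members, so the 10 genes are not independent measurements.

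Genes of mitosis were lower as a list in T24GR. Of 29 measured members 7 fell and 0 rose (10 and 1 adjusted over the list alone), but single arrays moved these counts. None fell without T24 replicate 1, 2 or 3 or without T24GR replicate 1, and 13 fell and 4 rose without T24GR replicate 3. HMMR, a spindle-associated protein, fell 5.45-fold (limma adjusted p = 0.023), DLGAP5, another spindle protein, 4.53-fold, and KIF11, a kinesin motor, 3.20-fold. On slides 1, 2 and 3 the differences were -2.89, -3.10 and -1.35 for HMMR, -2.41, -2.88 and -1.25 for DLGAP5 and -1.69, -2.26 and -1.08 for KIF11, and each kept its call under 2 of the 6 leave-outs. Whether RNA degradation, which stays open below, bears on these falls was not tested. The list median was -0.41, and -0.23, -0.24 and -0.57 on slides 1, 2 and 3 (camera adjusted p = 0.0045, and adjusted p = 0.60 with an estimated correlation).

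DNA repair genes were also lower as a list: 7 of 41 fell and 0 rose, or 12 and 3 adjusted over the list alone. Without T24 replicate 1, 2 or 3 none fell, without T24GR replicate 1 only 1 fell, and without T24GR replicate 3 19 fell and 8 rose. RAD50, a double-strand break sensor that lay in the dim area, fell 4.83-fold (limma adjusted p = 0.037), and TP53BP1, a double-strand break response gene, fell 2.31-fold. RAD50 differed by -2.82, -3.02 and -0.98 on the 3 slides and by -2.95 without T24GR replicate 3, and it kept its call under 2 of the 6 leave-outs and TP53BP1 under 3. Whether RNA degradation bears on the RAD50 fall was not tested either. The list median was -0.28, and -0.24, -0.39 and -0.31 on the 3 slides (camera adjusted p = 0.039, and adjusted p = 0.60 with an estimated correlation). By fry the list did not pass (fry adjusted p = 0.0536). The list's call ended without T24 replicate 3, T24GR replicate 1 or T24GR replicate 2 (camera adjusted p = 0.058, 0.065 and 0.051) and without the probes in the dim area (camera adjusted p = 0.0793). The alternative of the dim area was chosen after seeing the data.

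Interferon-stimulated genes were lower as a list, with 5 of 33 members lower and 0 higher (8 and 0 adjusted over the list alone). Only 1 was lower without T24 replicate 1, 2 or 3 or T24GR replicate 1, and 10 were lower and 2 higher without T24GR replicate 3. HERC5, a ligase for the ubiquitin-like ISG15 whose probe lay in the dim area and was well above background on 2 of 3 T24GR arrays, fell by at least 5.17-fold (limma adjusted p = 0.0069), and the antiviral genes IFIT2 and IFIT3 fell 3.50-fold and 3.09-fold, each with its call kept under 2 of the 6 leave-outs. The list median was -0.53, and -0.98, -0.18 and -0.12 on slides 1, 2 and 3 (camera adjusted p = 0.015, and adjusted p = 0.81 with an estimated correlation). By fry the list did not pass (fry adjusted p = 0.372). The call ended without T24 replicate 1 (camera adjusted p = 0.28) and without T24GR replicate 3 (camera adjusted p = 0.0879).

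**Figure D3:**
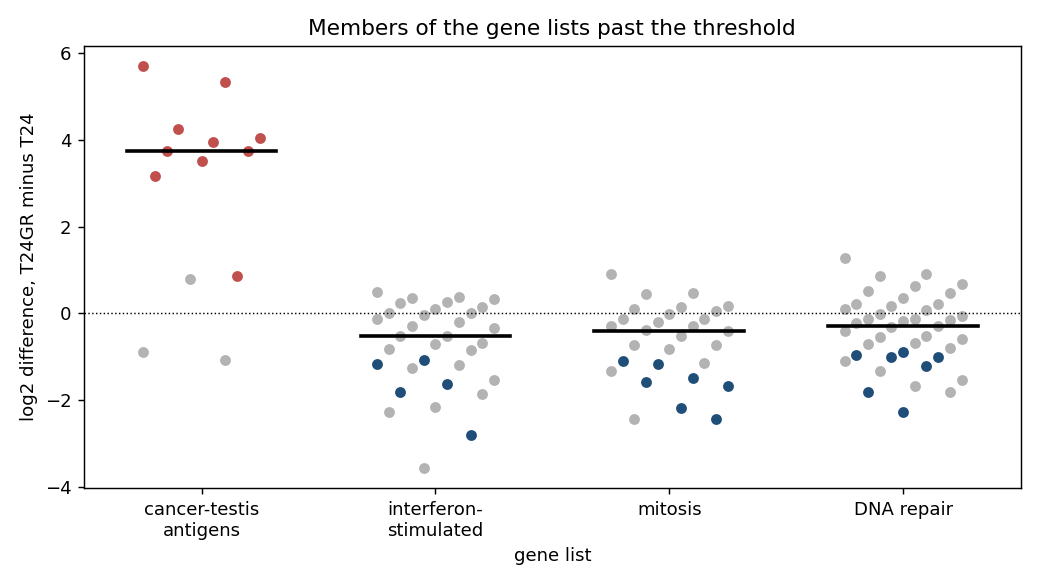
Log2 difference between T24GR and T24 (vertical axis) of each measured member of the 4 gene lists past the threshold; red points rose, blue points fell, grey points did not pass the limma threshold, and black lines are list medians. The medians were 3.74 for cancer-testis antigens, -0.53 for interferon-stimulated genes, -0.41 for mitosis and -0.28 for DNA repair.

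The remaining 25 tested lists did not pass the threshold (camera adjusted p from 0.0612 to 0.894). Some of them passed with camera under alternatives, and the steroid synthesis and basal urothelial lists passed by fry (fry adjusted p = 0.018 and 0.0039). Entries of the 25 lists called higher and lower, 46 and 56 in all, became 12 to 150 and 16 to 117 with 1 array left out. Of the genes named below, those called under every leave-out were ABCC3, ABCB1, AKR1C1, THY1, HOMER2, NNMT, NCOR1, UGT2B7, ABCC6, ABCB4, POLE2, BBC3, ITGB4, KRT14, CDH3, SMAD6, TNF, PPP1R15A, FGF1, NRG1, P4HA1 and LAPTM5. Among the genes named below, ABCC3, ABCB1, APAF1, SLC2A3, CCL2, CXCL6 and AKR1C1 were well above background on 2 of the 3 T24GR arrays, OCLN and PECAM1 on 1 of them, VWF on none of them, and THY1 on 2 of the 3 T24 arrays. Where such a gene was lower in the line with the missing arrays, the fold is a bound with signals raised to the background floor. Of 25 androgen-responsive genes 4 rose and 2 fell (4 and 7 adjusted over the list alone), with HOMER2 at 4.25-fold, NNMT, a methyltransferase of nicotinamide, at 4.22-fold and NDRG1 at 2.71-fold higher, and ELL2 and PDIA5 at 1.89-fold and 1.88-fold lower. Among 21 coregulators of hormone receptors 1 rose and 2 fell (1 and 1 adjusted over the list alone): the corepressor NCOR1 rose 3.12-fold, FOXA1 (dim area) fell 1.93-fold and NCOA4 1.55-fold (adjusted p = 0.0896 with the replicate block). The NCOR1 probes disagreed, with log2 differences from -0.0058 to 1.64, and the 2 PDIA5 probes had -0.91 and -0.27. Steroid synthesis and clearance enzymes had 0 rises and 2 falls among 12 (2 and 3 adjusted over the list alone). UGT2B7 fell by at least 3.05-fold and AKR1C1 by at least 9.23-fold. The 2 AKR1C1 probes had log2 differences of -3.28 and -2.83, and the bound is that of the brighter probe. With normexp and the 75th percentile the UGT2B7 log2 difference was -0.70 (limma adjusted p = 0.105), smaller than its bound. AKR1C1 and UGT2B7 have close paralogs. Among 11 drug efflux genes 2 rose and 3 fell, with the same counts adjusted over the list alone: ABCC6 and ABCB4 rose 5.46-fold and 4.23-fold, and ABCC3, ABCB1 (dim area) and ABCC5 fell by at least 16.7-fold, at least 4.54-fold and 2.43-fold. The ABCC5 probes differed, with log2 differences from -1.28 to -0.42.

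Cell-cycle and death genes moved in part. Among 32 DNA replication genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), with CCNE2 4.97-fold, POLE2 3.29-fold and RFC3 2.24-fold lower. Of 27 genes of nucleotide synthesis 2 rose and 1 fell, as also adjusted over the list alone: UCK1, a uridine-cytidine kinase, and ATIC rose 2.32-fold and 2.29-fold. Targets of p53 had 2 rises and 1 fall among 24 (2 and 1 adjusted over the list alone), with BBC3 up 5.64-fold, CDKN1A up 3.21-fold and CCNG1 down 1.98-fold. Of 33 apoptosis genes 2 rose and 2 fell (1 and 2 adjusted over the list alone): BBC3 and BCL2L11, both pro-apoptotic BCL2 family members, rose, the latter 1.54-fold (adjusted p = 0.0915 with the replicate block), while CASP1 fell 3.84-fold and APAF1 at least 2.32-fold. Normexp with the 75th percentile ended the calls of BCL2L11 and APAF1 (limma adjusted p = 0.0504 and 0.063), and median scaling ended that of BCL2L11 (limma adjusted p = 0.193), which kept its call under 1 of the 6 leave-outs. With normexp and the 75th percentile the APAF1 log2 difference was -0.50, smaller than its bound.

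In the differentiation lists, 3 of 10 basal urothelial genes fell and 0 rose (3 and 1 adjusted over the list alone): ITGB4 fell 39.6-fold, and KRT14 and CDH3 by at least 13.3-fold and at least 1.66-fold (camera adjusted p = 0.0612). The CDH3 difference turned to 0.016 log2 units with normexp background correction and the 75th percentile. In 13 luminal urothelial genes 2 rose and 3 fell (2 and 4 adjusted over the list alone), with FGFR3 2.88-fold higher and KLF5, GATA3 and FOXA1 3.51-fold, 2.26-fold and 1.93-fold lower. Epithelial junction genes had 4 falls and 0 rises among 19 (5 and 0 adjusted over the list alone), among them SPINT1 at 6.01-fold, EPCAM at 3.45-fold and OCLN at 2.43-fold or more, whose other probe had a log2 difference of -1.75. Mesenchymal genes had 1 rise and 3 falls among 18 (1 and 5 adjusted over the list alone): TAGLN rose 5.75-fold, MMP2 fell by at least 1.64-fold, LOX (dim area) 2.00-fold and COL5A2 1.88-fold. Stem cell genes had 2 rises and 4 falls among 14 (2 and 4 adjusted over the list alone), with THY1 at least 9.23-fold and KLF4 4.28-fold higher and POU5F1, MYC and HES1 2.51-fold, 2.28-fold and 1.93-fold lower. Targets of TGF-beta, SMAD and YAP had 4 rises and 3 falls among 20 (4 and 5 adjusted over the list alone): CCN2 rose 2.60-fold, TGFB2 2.39-fold and BAMBI 2.33-fold, and SMAD6 fell 6.95-fold, LTBP2 2.59-fold and THBS1 2.50-fold. Normexp with the 75th percentile ended the calls of OCLN, MMP2, LOX and HES1 (limma adjusted p = 0.708, 0.898, 0.064 and 0.189), normexp with quantile normalization that of MMP2 (limma adjusted p = 0.141) and median scaling that of TGFB2 (limma adjusted p = 0.0754). With normexp and the 75th percentile the log2 differences were -0.12 for OCLN and -0.058 for MMP2, smaller than their bounds. MMP2 kept its call under 1 of the 6 leave-outs.

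In the signalling and stress lists, 6 of 27 inflammatory genes rose and 5 fell, as also adjusted over the list alone: the cytokines TNF and IL6 rose 8.86-fold and 7.72-fold and ICAM1 6.46-fold, while the chemokines CCL2 (dim area), CXCL6 and CXCL5 fell by at least 8.82-fold, at least 8.19-fold and 3.47-fold. Unfolded protein and amino acid stress genes had 6 rises and 1 fall among 26 (8 and 1 adjusted over the list alone), with PPP1R15A at 4.87-fold, CEBPB at 2.85-fold and DDIT3 at 2.60-fold higher and DNAJC3 1.90-fold lower (adjusted p = 0.0546 with the replicate block). Of 29 EGF and FGF ligand and receptor genes 4 rose and 2 fell (5 and 3 adjusted over the list alone): FGF1 rose 9.10-fold, FGFBP1 2.32-fold, and NRG1 fell 4.70-fold and IGF1R 1.90-fold. The 2 FGF1 probes differed, at 0.12 and 3.19 log2 units. Hypoxia and glycolysis genes had 2 rises and 5 falls among 27 (3 and 6 adjusted over the list alone), with SLC2A3 1.86-fold higher and P4HA1, BNIP3 and P4HA2 4.76-fold, 2.52-fold and 2.23-fold lower. Sterol and fatty acid genes had 3 rises and 1 fall among 30 (2 and 1 adjusted over the list alone): SREBF1 rose 2.02-fold (adjusted p = 0.0537 with the replicate block) and INSIG1 1.90-fold. Of 22 NRF2 targets only AKR1C1 fell and 0 rose (1 and 0 adjusted over the list alone), and of 16 antigen presentation genes only B2M, in the dim area, fell, by 1.70-fold with adjusted p = 0.0581 with the replicate block (1 and 0 adjusted over the list alone). Median scaling ended the calls of SLC2A3, SREBF1 and INSIG1 (limma adjusted p = 0.108, 0.0723 and 0.0648), and normexp with quantile normalization that of SLC2A3 (limma adjusted p = 0.0549).

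Lists of reference genes and of other cell types completed the set. Of 14 reference genes RPL13A and TBP (dim area) were higher by 2.16-fold and 1.64-fold, TBP with adjusted p = 0.0727 with the replicate block and 0.131 with median scaling, and 0 fell (5 higher and 3 lower adjusted over the list alone), and the list median turned from 0.36 to -0.20 after quantile normalization, which ended the call of RPL13A (limma adjusted p = 0.0945). Of 6 leukocyte markers 1 fell, LAPTM5 by 4.10-fold, as also adjusted over the list alone. None of 6 endothelial markers was called (0 adjusted over the list alone), PECAM1 and VWF (dim area) among them (limma adjusted p = 0.20 and 0.41). The T24 arrays spread widely for both, with SDs of 2.78 for PECAM1 and 4.70 for VWF, against 1.72 and 0.43 in T24GR. On slides 1, 2 and 3 PECAM1 differed by 0.11, -5.94 and -2.61 and VWF by 0.25, -7.59 and 0.0023. The endothelial list median was 1.00, -2.79 and 0.52 on these slides. The only measured fibroblast marker was THY1. List medians and means had opposite signs for NRF2 targets (0.21 and -0.11), luminal genes (-0.18 and 0.15), stem cell genes (-0.22 and 0.08), leukocyte markers (0.44 and -0.19) and endothelial markers (0.037 and -0.34), and camera's direction was down for EGF and FGF genes, whose median was 0.018. By camera the direction was down for leukocyte and up for endothelial markers, and fry gave up for luminal genes.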

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

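The tests of T24 cells in a T24GR culture and of the dim area were settled only after the result was seen; the other tests here were chosen before.

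Among kept probes that have no gene symbol here, which the comparisons of genes leave out, 452 were higher and 356 lower in T24GR (limma). They stand out because they are a signal in data the gene counts do not use.

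The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 2393 genes, 1 of the 10 splits called as many, and the highest count of any other split was 0 (limma). At an unadjusted p under 0.05 the real split had 5560 genes and the other splits up to 1114. That highest count came from the split that put T24GR replicate 3 with T24 replicates 1 and 3.

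T24GR arrays differed more from one another than T24 arrays did. Their pairs had 2.90 times the median SD of T24 pairs, and 3.42 times after quantile normalization, which argues against array signal level as the whole source, and the pair without replicate 2 had 1.98 times the highest SD of a T24 pair, which argues against the dim area of that array as the whole source. For RNA degradation, the difference between T24GR replicates 2 and 3 was compared between 2 probes of a gene (3761 genes, which are not independent replicates). It correlated at a Pearson r of 0.406 and a Spearman rho of 0.608, both between the values foreseen with and without degradation. Probes in the dim area of replicate 2 were included, and a gene with only 1 probe inside it would lower the correlation without degradation. RNA degradation therefore stays open. T24 cells in the T24GR replicate 3 culture would bring every T24 transcript. In replicate 3, the 9 genes under 5% of the T24 level in T24GR replicates 1 and 2 had a median of 1.14% (0.114% to 4.39%). This argues against such a mixture, but that set was chosen after 2 sets of 50 genes had given 74.8% and 19.5%. Both values favoured mixing by the bound that the test was first given. The first set of 50 held genes at 51.1% in replicate 1 and 0.538% in replicate 2, and the second genes at 14.5% and 12.04%, so T24GR itself expressed many of them. A true difference between the cultures also stays open, untested.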

How the results depend on the processing

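The alternatives without T24GR replicates 1 and 2 and without probes in the dim area were chosen after seeing the data, and the others before. Without T24GR replicates 1 and 2 only 1 T24GR array is left, so the spread comes from the T24 arrays alone. That alternative enters only the CDA difference given above and the totals for named genes below. Counts of genes higher, lower, higher by at least 2-fold and lower by at least 2-fold were 828, 1738, 631 and 1345 with median scaling, 421, 250, 421 and 250 with no filter on dim probes (21593 genes tested), 618, 539, 591 and 527 with treat against a 1.2-fold change, and 744, 665, 440 and 368 without moderation. Normexp with quantile normalization gave 1753 lower and 561 higher by at least 2-fold, and leaving out T24GR replicates 1 and 2 gave 2448 lower. With each array left out, these counts were 241 to 4975, 170 to 3266, 241 to 2324 and 170 to 1854, lowest without T24 replicate 3 and highest without T24GR replicate 3. Treat asks for a larger change by construction; for the others the cause was not tested. With the replicate block, which is the slide, 1254 genes were higher and 1164 lower, 1970 of the 2393 genes kept their call, 7 named genes lost their call (adjusted p beside each in the report), and no other call of a named gene or list changed. Shifted lists numbered 7 with quantile normalization, with or without normexp, 3 to 5 with each array left out, and 0 with an estimated correlation. Lists that passed with camera only under alternatives were DNA replication (camera adjusted p from 0.00265 to 0.0472) and basal urothelial in 6 (0.0156 to 0.0423). So did hypoxia and glycolysis (camera adjusted p from 0.0222 to 0.0373) and, without T24GR replicate 2, amino acid stress (0.0346). By fry, the steroid synthesis and basal urothelial lists passed (fry adjusted p = 0.018 and 0.0039). Of 2481 values of named genes under alternatives, 2114 kept direction and side of the threshold, 363 lost the call, 3 gained it and 1 reversed: CDH3, at 0.016 with normexp and the 75th percentile. On T24GR replicate 2, 43.7% of spots were well above background, which limits what could be measured there.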

Other observations

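The imprinted, annexin and keratin lists and all tests of chromosomes were chosen only after the result was seen; the tests of DCK were chosen before.

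Of 29 measured imprinted genes 6 fell and 2 rose (8 and 3 adjusted over the list alone). Besides SGCE, PEG10 and MEST, H19, a noncoding RNA measured on 1 of 3 T24GR arrays, fell by at least 3.83-fold, INPP5F 2.04-fold and UBE3A 1.95-fold, while MKRN3, measured on 2 of 3 T24 arrays, rose at least 7.33-fold and CDKN1C, a cell-cycle inhibitor, 3.70-fold (limma adjusted p at most 0.0404). The 2 H19 probes had log2 differences of -2.67 and -1.47, and the bound is that of the brighter probe. For the imprinted list the camera adjusted p was 0.0196, and the adjusted p with an estimated correlation was 0.206. Of 22 annexins and keratins 5 fell and 1 rose (6 and 1 adjusted over the list alone): KRT23 fell by at least 2.30-fold along with KRT14, KRT17, ANXA10 and ANXA8L1, and KRT80 rose 2.18-fold (camera adjusted p = 0.0196, and adjusted p = 0.445 with an estimated correlation). Both lists were written around genes already seen to fall, so these tests are not independent evidence.

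DCK was lower in T24GR by at least 5.91-fold with 75th percentile scaling of the processed signal. Loss of the chromosome segment that holds it would lower its neighbours, but the 10 nearest measured genes had a median log2 difference of 0.18 (-3.47 to 3.27), which argues against a segment of that size and leaves a loss of DCK alone open. Of these 10 genes 3 were called lower and 1 higher, against 7.70% of all genes lower, and the nearest on each side, MOB1B and ADAMTS3, differed by 0.90 and 3.27. Scaling and signal level also stay open for the size: the DCK log2 difference was -3.55 with quantile normalization and -1.58 with normexp and quantile normalization, past the threshold in both, and DCK was near background in T24GR. Selection in gemcitabine is the biological difference the design names, and it was not tested apart from these.

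Genes of one chromosome shifted together. The median log2 difference was -0.71 on chromosome 13, -0.48 on 14 and -0.43 on 15, and 0.60 on 19, 0.46 on 9 and 0.38 on X. These 6 kept their signs on all 3 slides, but chromosome 19 had 0.71, 0.95 and 0.27 on slides 1, 2 and 3. Some other chromosomes changed sign: 16 had 0.36, 0.53 and -0.068, and 22 had 0.11, 0.31 and -0.33. Across chromosomes the medians correlated at 0.98 between slides 1 and 2, 0.88 between 1 and 3 and 0.78 between 2 and 3. Array scaling was argued against, since after quantile normalization the SD of chromosome medians was 4.77 times the highest of 1000 random assignments, as was gene length with expression level, whose removal left 0.873 of that SD. Medians of adjacent blocks of 20 genes correlated at 0.556 within chromosomes (highest of 200 shuffles 0.0983), so gains and losses of chromosome parts in T24GR are a candidate explanation. GC content was not tested, and shared regulation of neighbouring genes would also give such a correlation.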
